A study of Homo sapiens with 24 samples.

How the data were processed

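RNA abundance was measured by sequencing of polyA-selected RNA in 24 samples of BeWo cells, a human choriocarcinoma line that serves as a model of placental trophoblast. Forskolin, which activates adenylyl cyclase and so raises cAMP, is used to make these cells fuse into a syncytium. GCM1 is a transcription factor of the trophoblast lineage, and its mRNA was targeted here with small interfering RNA (siRNA), beside a non-targeting siRNA as control. Per the labels, DMSO was given at 0.1% for 48 h, forskolin at 50 µM for 48 h and siRNA for 24 h, and the combined groups received both in one order or the other. The labels give these durations in order but no time of harvest as such. They also do not say whether forskolin stayed on the cells during a later transfection, or whether the 3 samples of a group came from separate cultures. The p-values below therefore measure the spread between these samples, which may be technical.

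The deposited values are estimated counts per Ensembl gene. Per the submitters' processing notes, reads were quantified with kallisto on GRCh38. The version, the annotation release and the step from transcripts to genes are not given in the sources used here. The estimated counts were scaled by the authors from TPM by gene length and library size, per the name of the deposited table, so that they were not whole numbers and summed to between 18403033 and 27974576 per sample. They were rounded to whole numbers before use. Each column carried the title of one sample, and no column was left unused. Gene symbols were found for 56986 of the 57558 identifiers and 572 stayed without one. Coordinates are those of GENCODE release 29 on GRCh38, counted from 1, which holds 57437 of the identifiers and 18113 of the tested ones. Genes of the chorionic gonadotropin beta cluster (CGB1, CGB2, CGB3, CGB5, CGB7, CGB8), the pregnancy specific glycoproteins, CSH1 and CSH2, and ANXA8L1 have near-identical copies among which reads can be misassigned, so that values of single members are uncertain. The same holds for the readthrough gene RPS10-NUDT3 and for the antisense gene TUBA1B-AS1, since no strand setting is stated.

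The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with all 24 samples in a single fit of 8 group means, TMM scaling and no covariate. Genes were kept by filterByExpr (a minimum count of 10 and a minimum total of 15), which left 18139 genes holding at least 99.89% of the counts of every library. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested within each comparison, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values, with standard errors (SE) taken from the fold change and the F statistic. Levels are CPM with library sizes scaled by the TMM factors, as mean ± SD of 3 samples. Where a group was at or under 3 counts in all, its fold change is given as a lower bound computed from 3 counts over the group.

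The comparisons were forskolin against DMSO, GCM1 siRNA against control siRNA in 3 settings (without forskolin, before it and after it), forskolin against no forskolin in cells given control siRNA (in both orders), and 3 interactions that test whether the effect of GCM1 siRNA differed between settings. By the labels, total time also differed between forskolin and no forskolin in cells given control siRNA. Time since transfection differed between siRNA before forskolin and the other settings. The choices of comparisons, tests, gene lists, named genes and alternatives were made before the data were examined, apart from those said to be added. Named genes were GCM1, a panel of 11 genes (CGA, CGB3, CGB5, ERVW-1, ERVFRD-1, SDC1, HSD3B1, CYP19A1, INHA, PGF and OVOL1), and the 8 largest rises and 8 largest falls in each of the first 4 comparisons among called genes with a mean of at least 5 CPM, no overlap between the groups and an ordinary gene symbol. In each interaction the 5 largest rises and 5 largest falls were named by the same rule without the condition on overlap. From each gene list, up to 4 members with the smallest adjusted p and a mean of at least 1 CPM could be named.

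There were 21 gene lists covering trophoblast cell types, published GCM1 targets, cAMP response, steroid and cholesterol synthesis, cell cycle, stress responses, interferon, hypoxia, p53, transporters, cell junctions, TGF-beta, WNT, marker genes of other cell types, and mitochondrially encoded genes as a sign of RNA quality. For each list the members called up and down were counted, with adjustment over all genes tested and again adjusted over the list alone. Lists were tested as sets with camera (limma 3.58.1, inter-gene correlation preset at 0.01), repeated with an estimated correlation, and with fry. Set p-values were adjusted over the 21 lists for forskolin against DMSO, and over 23 sets for the siRNA comparisons and interactions, where the genes raised and the genes lowered by forskolin were added as sets. GCM1 siRNA comparisons shared no library with forskolin against DMSO or with each other, so overlaps between them carry no shared-control effect.

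Pairs of replicates were compared by a chi-square test of their counts over genes with a summed count of at least 20. The statistic per gene was between 5.63 and 13.0 in pairs without replicate 1 of the group given GCM1 siRNA before forskolin and between 29.8 and 32.0 in pairs with it, so that no pair met the condition for being merged as 1 sample. As estimated counts carry more than counting noise, this does not show that the samples were separate cultures. The procedure was tested on simulated counts with 200 changed genes, drawn at the mean of each gene over all samples and at the library sizes of these samples. The dispersions were those estimated by edgeR, which may favour edgeR over DESeq2. Far fewer genes changed than with forskolin in the real samples. For GCM1 siRNA without forskolin, edgeR recovered 55.2% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 90.9% of those changed 4-fold among 17676 simulated genes tested, and 6.41% of its calls were false, against 20.2% for DESeq2. For the interaction before forskolin the recovery was 28.4%, 52.2% and 92.4%. For the interaction after forskolin it was 32.8%, 67.2% and 86.4%, and 7.46% of the calls were false. In the simulated lists, 1 list shifted 1.2-fold was found with an estimated correlation (p = 1.61e-09) and 0 of 20 unshifted lists passed by camera at an unadjusted p under 0.05. Genes were drawn independently of each other, so the simulation could not show how often correlated lists pass at the preset correlation.

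Alternatives were DESeq2 1.42.0, limma-voom, DESeq2-type size factors (RLE) or library totals in place of TMM, no low-count filter or a minimum mean of 5 CPM, only the compared groups in the fit, the replicate number as a block, an added 2-fold minimum, and the omission of each library in turn. Added after the data were seen were the counts of list members without libraries that stood apart, and the response to forskolin in cells given GCM1 siRNA. Raw reads were not used here, so that mapping, isoforms and sequence variants were not examined.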

Results

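The 24 samples formed 8 groups of 3, named here as the DMSO group, the forskolin group, the control siRNA group, the GCM1 siRNA group, the control siRNA-then-forskolin and GCM1 siRNA-then-forskolin groups, and the forskolin-then-control siRNA and forskolin-then-GCM1 siRNA groups. Principal component 1 of the tested genes held 48.7% of the variance and followed forskolin. The DMSO, control siRNA and GCM1 siRNA samples lay between -86.3 and -77.0 on it, and the forskolin and control siRNA-then-forskolin samples between 70.5 and 88.7. Samples given siRNA after forskolin lay between 35.9 and 51.0, and those given GCM1 siRNA before forskolin between 1.25 and 5.73. Replicate 1 of the GCM1 siRNA-then-forskolin group stood apart. It had counts for 22007 genes (23995 to 26805 in the other libraries). At 10 counts or more it had 15938 genes, against 15248 and 15844 in its group mates, so only genes with few counts were missing. In it 18S ribosomal RNA made up 1.82% of counts (0.573% to 0.619% in its group mates, but 1.49% in DMSO replicate 1, the highest of the others). RN7SL RNA made up 0.108% (at most 0.0342% in the others).

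GCM1 (ENSG00000137270, chromosome 6, 53126964 to 53148829, minus strand) was expressed in every sample. In CPM, replicates 1 to 3 gave 171, 169 and 170 with DMSO, 552, 541 and 564 with forskolin, 194, 189 and 191 with control siRNA, and 119, 109 and 112 with GCM1 siRNA. The control siRNA-then-forskolin samples gave 506, 526 and 532, and the GCM1 siRNA-then-forskolin samples 236, 209 and 206. With forskolin first, the samples gave 241, 223 and 228 after control siRNA and 120, 117 and 123 after GCM1 siRNA. Forskolin raised GCM1 3.25-fold over DMSO (log2 fold change 1.70, SE 0.0493, adjusted p = 9.18e-19). GCM1 siRNA lowered it by 0.76 on the log2 scale without forskolin (SE 0.0489, adjusted p = 5.82e-10), by 1.27 before forskolin (SE 0.0487, adjusted p = 1.2e-15) and by 0.94 after it (SE 0.049, adjusted p = 1.14e-11).

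**Figure D1:**
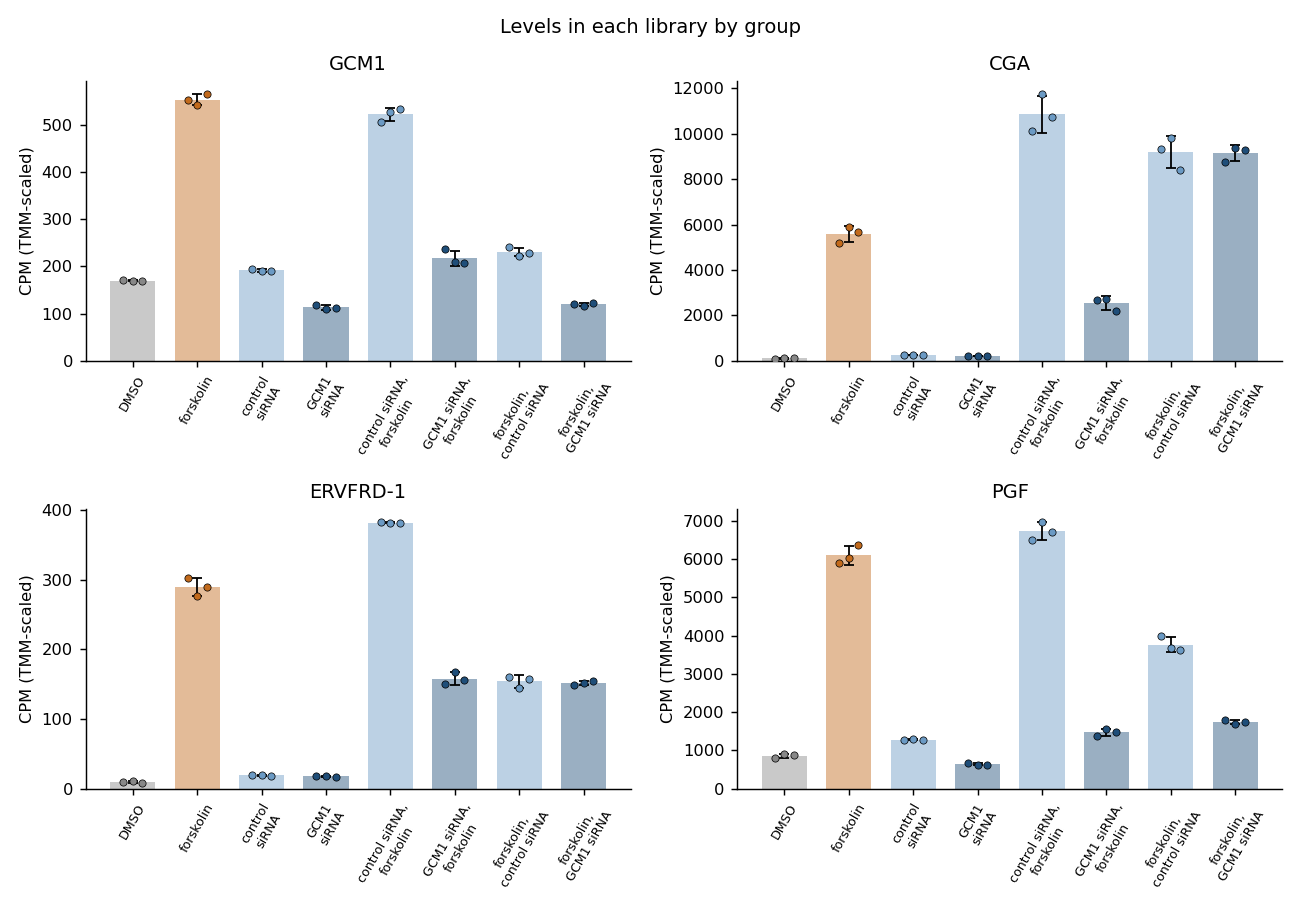
GCM1, CGA, ERVFRD-1 and PGF in CPM in each library of the 8 groups. Bars show the mean and whiskers the SD of 3 samples.

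Forskolin against DMSO raised 30 of 37 measured genes of the syncytiotrophoblast, the fused outer layer of the placenta. CGA, the alpha subunit of chorionic gonadotropin, rose from 105 ± 7.13 to 5582 ± 369 CPM (53.2-fold, log2 5.73, SE 0.0876, adjusted p = 1.87e-23, n = 3 each), and CGB3 from 9.34 ± 2.37 to 1375 ± 86.4 (147-fold, SE 0.132, adjusted p = 4.02e-22). The retroviral fusion genes ERVFRD-1 (8.76 ± 1.44 to 289 ± 12.7, 33.1-fold) and ERVW-1 (138 ± 11.9 to 619 ± 18.6, 4.49-fold) rose, as did the aromatase gene CYP19A1 (20 ± 2.59 to 961 ± 34.6, 48.3-fold). The epithelial repressor OVOL2 fell from 10.1 ± 1.42 CPM to at most 3 counts in all, at least 194-fold lower (adjusted p = 4.85e-12), while its relative OVOL1 rose 15-fold (75.6 ± 5.3 to 1136 ± 48.4). EPCAM, a surface marker of mononuclear trophoblast, fell 23.2-fold, from 111 ± 4.72 to 4.75 ± 0.213 (adjusted p = 7.16e-22).

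In all, forskolin raised 5280 genes and lowered 5042 of 18139 (51.2% of calls up). With library totals in place of TMM factors, 3374 rose and 7735 fell (30.4% up), since the median log2 fold change moved by -0.35. TMM factors ran from 1.14 to 1.15 in the DMSO group. Among the largest rises were PRR9 (log2 8.57, SE 0.237, 0.216 ± 0.107 to 83.1 ± 5.77), the calcium channel TRPV2 (7.73, SE 0.0968), the glutamine transporter SLC38A3 (7.05, SE 0.148), DEGS2 (7.29, SE 0.474), CGB8 (6.81, SE 0.104) and CGB5 (6.80, SE 0.145). Among the largest falls were the protease PRSS22 (-5.02, SE 0.188), ENC1 (-4.71, SE 0.209), the natriuretic peptide NPPB (-4.63, SE 0.229, 11.3 ± 1.8 to 0.456 ± 0.0779) and the fatty acid desaturase FADS2 (-4.49, SE 0.107, 354 ± 36.1 to 15.7 ± 2.4). Further rises were PGF, 7.13-fold (856 ± 56.2 to 6103 ± 252), SDC1, 7.82-fold (170 ± 10.4 to 1328 ± 44.9), INHA (log2 5.60, SE 0.209) and HSD3B1 (2.23, SE 0.373), the last at only 4.25 ± 0.832 CPM.

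Of the 37 measured syncytiotrophoblast genes, 30 rose and 3 fell with forskolin (camera adjusted p = 1.24e-13), and of 11 measured published GCM1 targets 11 rose (adjusted p = 1.24e-13). Most of these targets were also in the syncytiotrophoblast list. Pregnancy specific glycoproteins numbered 5, of which 4 rose, among them PSG9 (4.64, SE 0.407) and PSG3 (6.96, SE 0.808) (adjusted p = 0.0346, but 0.0912 with an estimated correlation). Of 18 retroviral envelope and fusion genes 10 rose, with ERVV-1 (5.30, SE 0.104) and ERVV-2 (5.21, SE 0.102), and 5 fell, among them the syncytin receptor SLC1A5 (-2.78, SE 0.0636) (adjusted p = 0.0452, but 0.227 with an estimated correlation and 0.0573 without DMSO replicate 1). The 29 cytotrophoblast and stem genes were split, 10 up and 16 down (adjusted p = 0.202), with rises of TFAP2C (1.99, SE 0.0514) and GATA3 (1.55, SE 0.0508) beside the fall of EPCAM. Extravillous trophoblast genes mostly rose, 18 of 26 with 4 falls (adjusted p = 1.88e-05), including ADAM19 (2.73, SE 0.0509) and HTRA4 (1.07, SE 0.0334). Of 13 mitochondrially encoded genes 10 rose and 0 fell (adjusted p = 0.0109, but 0.474 with an estimated correlation), while their share of counts was 2.60% ± 0.152 with forskolin and 2.58% ± 0.210 with DMSO.

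Of 20 early genes of the cAMP response, 17 rose and 2 fell with forskolin (adjusted p = 1.47e-08), among them DUSP1 (3.28, SE 0.082), NR4A3 (5.05, SE 0.147) and FOSB (4.55, SE 0.157). Steroid synthesis genes rose in 9 and fell in 4 of 17 cases (adjusted p = 0.0245, but 0.240 with an estimated correlation), led by CYP11A1 (3.02, SE 0.0562) and HSD11B2 (6.03, SE 0.133), whereas cholesterol synthesis genes had 15 down and 5 up of 25 (adjusted p = 0.00116, but 0.0674 with an estimated correlation), with DHCR24 (-2.67, SE 0.0679) and FDFT1 (-3.06, SE 0.0935). Cell cycle genes fell in 25 of 40 cases and rose in 8 (adjusted p = 0.000511, but 0.0674 with an estimated correlation), with FOXM1 (-2.67, SE 0.0683) and HMGB2 (-2.66, SE 0.0756) against a rise of RRM2 (3.03, SE 0.0784). The unfolded protein and integrated stress response list had 20 of 25 genes up and 4 down (adjusted p = 1.19e-07), including HERPUD1 (2.68, SE 0.0615) and ATF3 (3.41, SE 0.118). Interferon response genes had 10 down and 3 up of 22 (adjusted p = 0.0109, but 0.0674 with an estimated correlation), among them STAT1 (-2.23, SE 0.0695) and IRF1 (-3.20, SE 0.177). Hypoxia genes had 16 up and 4 down of 23 (adjusted p = 0.000275, but 0.0674 with an estimated correlation), with NDRG1 (5.35, SE 0.108) and BHLHE40 (3.83, SE 0.0781).

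Placental transporters rose in 18 and fell in 8 of 29 cases (adjusted p = 0.000114), with the iron exporter SLC40A1 (4.72, SE 0.129) and the amino acid carrier SLC7A8 (3.41, SE 0.0968). TGF-beta and activin genes rose in 16 and fell in 5 of 23 cases (adjusted p = 3.07e-05), with ID2 (3.57, SE 0.0781) and TGFB1 (3.40, SE 0.0805). The p53 list had 8 up and 12 down of 22 (adjusted p = 0.318), with PMAIP1 (3.32, SE 0.0849) and CDKN1A (2.01, SE 0.0556) up. Epithelial junction and keratin genes were split, 11 up and 13 down of 26 (median log2 -0.20, mean 0.54, adjusted p = 0.761), with KRT23 up (5.88, SE 0.0969) and CDH1 down (-1.28, SE 0.0519). For WNT genes, 7 up and 8 down of 23, the median was 0.09 with TMM and -0.25 with library totals (adjusted p = 0.823). Of 7 fibroblast and endothelial markers 2 rose and 1 fell (median 0.02, but -0.33 with library totals, adjusted p = 0.888), and of 3 blood markers 1 fell, CSF1R (-0.66, SE 0.0611) (adjusted p = 0.761). In a count added after the data were seen, without DMSO replicate 1, 1 fibroblast or endothelial marker rose and 0 fell, and 1 cAMP response gene fell in place of 2. Adjusted over the list alone the counts were the same, apart from 16 cholesterol genes down, 9 cell cycle genes up, 11 interferon genes down, 14 junction genes down and 17 TGF-beta genes up.

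GCM1 siRNA without forskolin changed far fewer genes, 178 up and 283 down against control siRNA. PGF, the placental growth factor, fell 2.01-fold from 1278 ± 20.9 to 637 ± 23.1 CPM (log2 -1.005, SE 0.0512, adjusted p = 2.98e-11, n = 3 each), and OVOL1 from 113 ± 4.73 to 72.6 ± 1.9 (-0.64, SE 0.0611, adjusted p = 4.73e-07). The transcription cofactor LMO2 fell from 40 ± 3.47 to 16.2 ± 3.22 (-1.31, SE 0.115) and LZTS1 from 15.6 ± 0.641 to 5.97 ± 0.965 (-1.39, SE 0.136). The progenitor factor TP63 rose from 14.9 ± 0.733 to 28.7 ± 0.329 (0.95, SE 0.185, adjusted p = 0.00385). ERVW-1 did not change, 175 ± 2.91 against 175 ± 10.1 (adjusted p = 1).

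Other rises without forskolin were ITGAM (1.30, SE 0.325), SLC12A3 (1.11, SE 0.227), FBXL16 (1.01, SE 0.155), WNT6 (0.99, SE 0.25), RIPOR2 (0.93, SE 0.122), SLC34A2 (0.91, SE 0.163) and KIF13B (0.90, SE 0.164). Other falls were SPIN4 (-3.59, SE 0.884), FAM163B (-1.52, SE 0.295), ALG14 (-1.37, SE 0.359), CHRM4 (-1.31, SE 0.161), SLC8A3 (-1.17, SE 0.178), TNFAIP3 (-1.07, SE 0.176), CGA (-0.27, SE 0.0723, adjusted p = 0.0441) and CGB5 (-0.45, SE 0.118, adjusted p = 0.0389). Not called were CGB3 (-0.38, adjusted p = 0.0774, but 0.0123 by DESeq2 and 9.82e-07 without the low-count filter), SDC1 (adjusted p = 0.916), INHA (0.495), CYP19A1 (0.647), HSD3B1 (0.459) and ERVFRD-1 (0.646). WNT6, SPIN4 and CGA each lost their calls when any single library of the 6 was left out (adjusted p up to 0.173, 0.128 and 0.184), and CGA also with RLE factors (0.0558) and library totals (0.0596). Among single omissions, ITGAM kept its call only for that of GCM1 siRNA replicate 2 (up to 0.175 for the others) and CGB5 only for that of GCM1 siRNA replicate 3 (up to 0.24). ALG14 lost its call without replicate 1 or 2 of either group (up to 0.268), and SLC12A3 without control siRNA replicate 3 (0.0624). The count of 461 genes fell to 287 and 300 without control siRNA replicates 1 and 3, and to 276 and 294 without GCM1 siRNA replicates 2 and 3. With library totals 269 genes rose and 225 fell (54.5% up, against 38.6% with TMM).

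Without forskolin, 0 of 37 syncytiotrophoblast genes rose and 7 fell with GCM1 siRNA, or 12 adjusted over the list alone (camera adjusted p = 2.6e-06, but 0.0541 with an estimated correlation). They included CGB8 (-0.49, SE 0.0834) and the leptin gene LEP (-0.69, SE 0.154). Of 11 published GCM1 targets 5 fell and 0 rose, or 7 down adjusted over the list alone (adjusted p = 3.81e-09). Extravillous genes fell in 9 of 26 cases and 0 rose, or 11 down and 1 up adjusted over the list alone (adjusted p = 5.05e-15), with CCNE1 (-0.79, SE 0.0478), ERBB2 (-0.79, SE 0.07) and ASCL2 (-0.75, SE 0.0744). Cytotrophoblast and stem genes rose in 6 of 29 cases with 1 fall, or 12 and 2 adjusted over the list alone (adjusted p = 4.02e-08), among them EPCAM (0.63, SE 0.0675) and TEAD4 (0.61, SE 0.099). Junction genes rose in 3 of 26 cases, or 5 adjusted over the list alone, and 0 fell (adjusted p = 8.32e-05), with CLDN3 (0.71, SE 0.162). Of 22 interferon genes 2 rose, or 3 adjusted over the list alone, and 0 fell (adjusted p = 0.000157), with IFI6 (0.55, SE 0.0904) and STAT1 (0.33, SE 0.0638). For the 13 mitochondrially encoded genes, 0 were called (adjusted p = 0.269).

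Stress response genes without forskolin had 0 up and 2 down of 25 (adjusted p = 0.00721, but 0.273 with an estimated correlation), with HSPA5 (-0.50, SE 0.0412). The p53 list had 0 up and 3 down of 22 (adjusted p = 0.000231, but 0.0502 with an estimated correlation), with GADD45A (-0.32, SE 0.0525). Hypoxia genes had 1 up and 3 down of 23 (adjusted p = 0.0291, but 0.274 with an estimated correlation), and TGF-beta genes 0 up and 3 down of 23, or 1 and 4 adjusted over the list alone (adjusted p = 0.0116, but 0.0541 with an estimated correlation), with TGFB1 (-0.51, SE 0.0769). Cholesterol genes had 1 up and 1 down of 25 (median 0.11, adjusted p = 0.00441, but 0.103 with an estimated correlation). WNT genes had 2 up and 2 down of 23, or 2 and 3 adjusted over the list alone (adjusted p = 0.269), with WNT10B at -0.98 (SE 0.0814). Retroviral genes had 0 up and 1 down of 18, or 1 and 3 (adjusted p = 0.269), cAMP genes 0 up and 2 down of 20, or 1 and 2 (adjusted p = 0.202), and steroid genes 1 up and 2 down of 17, or 1 and 3 (adjusted p = 0.176), the second counts adjusted over the list alone. So counted, 1 up and 1 down of 40 cell cycle genes (adjusted p = 0.997) were called, against 0 over all genes, and 3 up and 5 down of 29 transporters (adjusted p = 0.802), against 0 up and 3 down. Pregnancy specific glycoproteins had 0 called of 5 (adjusted p = 0.895), fibroblast and endothelial markers 1 down of 7, CDH5 (-0.26, SE 0.0516) (adjusted p = 0.433), and blood markers 0 of 3, or 1 down adjusted over the list alone (adjusted p = 0.00856, but 0.165 without the low-count filter). The other lists kept their counts when adjusted over the list alone.

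GCM1 siRNA before forskolin changed 8271 genes against control siRNA before forskolin, 4087 up and 4184 down. CGA was 4.27-fold lower, 2543 ± 290 against 10854 ± 819 CPM (log2 -2.09, SE 0.0736, adjusted p = 2.47e-16, n = 3 each), CGB3 5.79-fold lower, 415 ± 30.9 against 2404 ± 167 (-2.53, SE 0.1, adjusted p = 1.92e-15), and PGF 4.59-fold lower, 1467 ± 83.2 against 6728 ± 238 (-2.20, SE 0.0527, adjusted p = 5.37e-19). ERVFRD-1 fell from 382 ± 0.93 to 158 ± 8.83 and ERVW-1 from 781 ± 41.9 to 341 ± 27.4. EPCAM was 15.3-fold higher, 98.5 ± 4.07 against 6.43 ± 0.18 (3.93, SE 0.0843, adjusted p = 1.12e-19), and NPPB rose from 0.514 ± 0.0738 to 14.9 ± 3.17 (4.83, SE 0.226). OVOL1 changed little, 882 ± 53.7 against 1136 ± 25.7 (-0.36, SE 0.0582, adjusted p = 1.66e-05, but -0.09 with library totals, adjusted p = 0.188).

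Further rises before forskolin were ANGPTL2 (4.48, SE 0.433), EMILIN2 (3.91, SE 0.0994, 17.5 ± 0.799 to 262 ± 20.4), RFLNA (3.70, SE 0.359), the oxidised lipid receptor OLR1 (3.64, SE 0.179), GALNT6 (3.57, SE 0.32) and the junction gene PLEKHA7 (3.56, SE 0.257). Further falls were BGN (-3.41, SE 0.438), PKP2 (-3.20, SE 0.344), CGB1 (-3.18, SE 0.416), TCF15 (-3.15, SE 0.232), ANXA1 (-3.05, SE 0.133), CGB2 (-3.04, SE 0.433), the TNF receptor TNFRSF1B (-3.03, SE 0.109, 910 ± 50.4 to 111 ± 10.4) and ABLIM2 (-2.89, SE 0.325). Of the panel, SDC1 (-1.80, SE 0.0546), INHA (-2.20, SE 0.151), CYP19A1 (-1.45, SE 0.0867), CGB5 (-2.47, SE 0.115) and HSD3B1 (-1.84, SE 0.35) also fell. With library totals 6936 genes rose and 2299 fell (75.1% up, against 49.4% with TMM), as the median log2 fold change moved by 0.28. TMM factors were between 0.8 and 0.845 in the control siRNA-then-forskolin group, where the 50 most abundant genes held 17.8% of counts.

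Of 37 syncytiotrophoblast genes, 34 fell and 1 rose with GCM1 siRNA before forskolin, or 34 and 2 adjusted over the list alone (camera adjusted p = 2.63e-22), and of 11 published GCM1 targets 11 fell (adjusted p = 6.6e-17). The 5 pregnancy specific glycoproteins fell, among them PSG9 (-2.09, SE 0.313) (adjusted p = 0.00846, but 0.0644 by DESeq2). Retroviral envelope and fusion genes had 9 down and 3 up of 18, or 10 and 4 adjusted over the list alone (adjusted p = 0.00846, but 0.103 with an estimated correlation), with ERVV-1 (-2.22, SE 0.0849) down and SLC1A5 (2.01, SE 0.0643) up. Cytotrophoblast and stem genes rose in 19 and fell in 8 of 29 cases, or 19 and 9 adjusted over the list alone (adjusted p = 0.000263), with KRT7 (1.36, SE 0.0565) and TEAD4 (2.74, SE 0.116) up. Extravillous genes fell in 16 and rose in 4 of 26 cases (adjusted p = 5.62e-06), with HTRA4 (-1.67, SE 0.0339) and NOTCH1 (-2.25, SE 0.107). Mitochondrially encoded genes fell in 6 of 13 cases (median -0.26, but 0.02 with library totals, adjusted p = 0.0233, but 0.485 with an estimated correlation). In an analysis added after the data were seen, replicate 1 of the GCM1 siRNA-then-forskolin group was left out. Then 33 syncytiotrophoblast genes, 4 pregnancy specific glycoproteins and 4 mitochondrial genes fell, 18 cytotrophoblast genes rose, and no list count of this comparison moved by more than 2.

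The cAMP response list had 15 down and 3 up of 20 (adjusted p = 0.000142), with FOSB (-2.26, SE 0.133) and DUSP1 (-1.27, SE 0.0735) down and AKAP12 (2.84, SE 0.108) up. Hypoxia genes fell in 18 and rose in 3 of 23 cases (adjusted p = 8.47e-08), with NDRG1 (-2.12, SE 0.0892) and ADM (-1.42, SE 0.0603). Stress response genes fell in 19 and rose in 2 of 25 cases, or 19 and 3 adjusted over the list alone (adjusted p = 6.63e-08), with DDIT4 (-1.77, SE 0.0739) and PDIA4 (-0.79, SE 0.0409). Interferon genes rose in 12 of 22 cases with 1 fall, or 13 and 1 adjusted over the list alone (adjusted p = 0.00282), with STAT1 (1.09, SE 0.0698) and HERC5 (2.36, SE 0.159) up and ISG15 (-1.51, SE 0.103) down. Cell cycle genes rose in 22 and fell in 7 of 40 cases (adjusted p = 0.000235, but 0.0508 with an estimated correlation), with FOXM1 (1.87, SE 0.068) up and RRM2 (-1.55, SE 0.074) down. Cholesterol genes rose in 14 and fell in 5 of 25 cases (adjusted p = 0.0364, but 0.211 with an estimated correlation and 0.0503 by DESeq2), with FDFT1 (1.64, SE 0.0919).

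Steroid genes had 5 up and 7 down of 17 with GCM1 siRNA before forskolin (median -0.06, but 0.22 with library totals, adjusted p = 0.213), with STS up (0.81, SE 0.0513). Transporters had 8 up and 15 down of 29 (adjusted p = 0.0145, but 0.137 with an estimated correlation), with SLCO4A1 (-2.08, SE 0.0883). WNT genes had 11 up and 7 down of 23 (adjusted p = 0.0282, but 0.166 with an estimated correlation, 0.0684 without GCM1 siRNA-then-forskolin replicate 1 and 0.0527 without control siRNA-then-forskolin replicate 2), with WNT7A (2.23, SE 0.0991) and SFRP1 (1.47, SE 0.0531). TGF-beta genes had 8 up and 12 down of 23 (adjusted p = 0.0824, but 0.00363 by DESeq2), with TGFBR2 (-1.73, SE 0.0597). The p53 list had 10 up and 7 down of 22 (adjusted p = 0.713), with BTG2 (1.56, SE 0.0934) up and CDKN1A (-1.48, SE 0.0545) down. Junction genes had 8 up and 11 down of 26, or 9 and 11 adjusted over the list alone (median 0.02, camera direction down, adjusted p = 0.985). Of 7 fibroblast and endothelial markers 2 rose (adjusted p = 0.444), among them COL1A1 (1.75, SE 0.198), and of 3 blood markers 0 were called (adjusted p = 0.705). The lists for which no second count is given had the same counts adjusted over the list alone.

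GCM1 siRNA after forskolin changed 840 genes, 345 up and 495 down, against control siRNA after forskolin. PGF fell 2.16-fold, from 3760 ± 196 to 1742 ± 55.4 CPM (log2 -1.11, SE 0.0511, adjusted p = 2.25e-12, n = 3 each), and OVOL1 from 397 ± 33.5 to 256 ± 9.32 (-0.63, SE 0.059, adjusted p = 2.08e-07). CGA did not change, 9135 ± 344 against 9177 ± 698 (-0.01, adjusted p = 0.986). The Notch target NRARP fell from 29 ± 1.84 to 12.7 ± 0.747 (-1.19, SE 0.116, adjusted p = 4.21e-07) and N4BP3 from 152 ± 5.28 to 66.7 ± 2.37 (-1.18, SE 0.0594). TP63 rose from 4.93 ± 0.26 to 9.32 ± 1.46 (0.91, SE 0.202, adjusted p = 0.00748).

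Other rises after forskolin were PRR15 (1.13, SE 0.177), PTPRG (1.12, SE 0.203), OCLN (1.03, SE 0.225), PTBP2 (0.99, SE 0.263), TBCK (0.99, SE 0.25), KRT24 (0.96, SE 0.27) and BAMBI (0.89, SE 0.184). Other falls were LINC01451 (-1.61, SE 0.113), PTPRE (-1.21, SE 0.13), KIF12 (-1.19, SE 0.232), OSGIN1 (-1.18, SE 0.213), VGLL3 (-1.16, SE 0.328), COL27A1 (-1.16, SE 0.142, 448 ± 54.3 to 201 ± 17.7), SDC1 (-0.31, SE 0.053) and CGB3 (-0.35, SE 0.0947, adjusted p = 0.0307). Not called were CGB5 (adjusted p = 0.198, but 0.000116 without the low-count filter), ERVW-1 (0.0899, but 0.0217 by DESeq2), INHA (0.95), CYP19A1 (0.729), HSD3B1 (0.759) and ERVFRD-1 (0.943). KRT24 and VGLL3 lost their calls when any single library of the 6 was left out (adjusted p up to 0.173 and 0.171), and KRT24 without the low-count filter (0.0662). PTBP2 kept its call only on omission of forskolin-then-GCM1 siRNA replicate 3 (up to 0.139 for the others) and CGB3 only on that of forskolin-then-control siRNA replicate 3 (up to 0.165). OCLN lost its call without replicate 3 of the GCM1 siRNA group or of the control (0.0728 and 0.0561), and TBCK without replicate 3 of the GCM1 siRNA group (0.199) or control replicates 1 and 2 (0.116 and 0.0637). The count of 840 fell to 554 and 546 without forskolin-then-GCM1 siRNA replicates 2 and 3, and to 546 and 544 without control replicates 1 and 3. With library totals 511 genes rose and 422 fell (54.8% up, against 41.1% with TMM).

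After forskolin, 9 of 37 syncytiotrophoblast genes fell with GCM1 siRNA and 0 rose, or 13 down adjusted over the list alone (camera adjusted p = 1.6e-11), with ERVV-1 (-0.41, SE 0.0812). Published GCM1 targets had 5 down and 0 up of 11, or 7 down adjusted over the list alone (adjusted p = 5.48e-11), with MFSD2A (-1.28, SE 0.286). Extravillous genes had 8 down and 1 up of 26, or 9 and 1 adjusted over the list alone (adjusted p = 4.17e-07), with CCNE1 (-0.78, SE 0.0477), SNAI1 (-0.79, SE 0.0676) and ERBB2. TGF-beta genes had 5 down and 1 up of 23, or 7 and 1 adjusted over the list alone (adjusted p = 0.00294), with TGFB1 (-0.52, SE 0.0716). Cytotrophoblast genes had 7 up and 3 down of 29, or 12 and 4 adjusted over the list alone (adjusted p = 0.0168, but 0.194 with an estimated correlation), with EPCAM (0.83, SE 0.073) and TEAD4 (0.78, SE 0.101) up and GATA2 (-0.41, SE 0.0439) down. Junction genes had 3 up and 0 down of 26, or 4 up adjusted over the list alone (adjusted p = 0.00339, but 0.157 with an estimated correlation), with CDH1 (0.36, SE 0.0514). Interferon genes had 5 up and 0 down of 22 (adjusted p = 0.0168, but 0.0872 with an estimated correlation), with HERC5 (0.69, SE 0.133), and cell cycle genes 4 up and 2 down of 40, or 6 and 2 adjusted over the list alone (adjusted p = 0.000113, but 0.0641 with an estimated correlation), with HMGB2 (0.44, SE 0.0707). Of 13 mitochondrially encoded genes 0 were called (adjusted p = 0.0527, but 0.0145 with library totals and 0.0263 without the low-count filter).

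In the remaining lists after forskolin, the second counts are those adjusted over the list alone. Retroviral genes had 5 up and 3 down of 18, then 5 and 4 (median -0.02, but 0.01 with library totals, adjusted p = 0.942), and steroid genes 1 and 1 of 17, then 2 and 2 (median -0.02, but 0.01 with library totals, adjusted p = 0.942). The cAMP list had 0 up and 3 down of 20, then 1 and 3 (adjusted p = 0.595), with FOSB (-0.98, SE 0.13) and SIK1 (-0.80, SE 0.137). Stress response genes had 2 and 2 of 25, then 3 and 5 (adjusted p = 0.0871), with HSPA5 (-0.27, SE 0.0411), and cholesterol genes 1 and 1 of 25, then 3 and 1 (adjusted p = 0.192). Hypoxia genes had 3 up and 2 down of 23, then 4 and 2 (adjusted p = 0.14, but 0.0395 with library totals and 0.0114 without the low-count filter), with CA12 (0.50) up and ADM (-0.33) down. Transporters had 3 up and 4 down of 29, then 4 and 4 (adjusted p = 0.729), and WNT genes 1 and 1 of 23, then 4 and 1 (median -0.05, mean 0.05, adjusted p = 0.942), with WNT10B (-0.95, SE 0.0869). The p53 list had 0 called of 22 (adjusted p = 0.41) and the pregnancy specific glycoproteins 0 of 5 (adjusted p = 0.594). Of 7 fibroblast and endothelial markers 1 fell, CDH5 (-0.43, SE 0.0519) (median -0.18, mean 0.15, adjusted p = 0.233), and of 3 blood markers 1, CSF1R (-0.25, SE 0.0607) (adjusted p = 0.136).

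**Figure D2:**
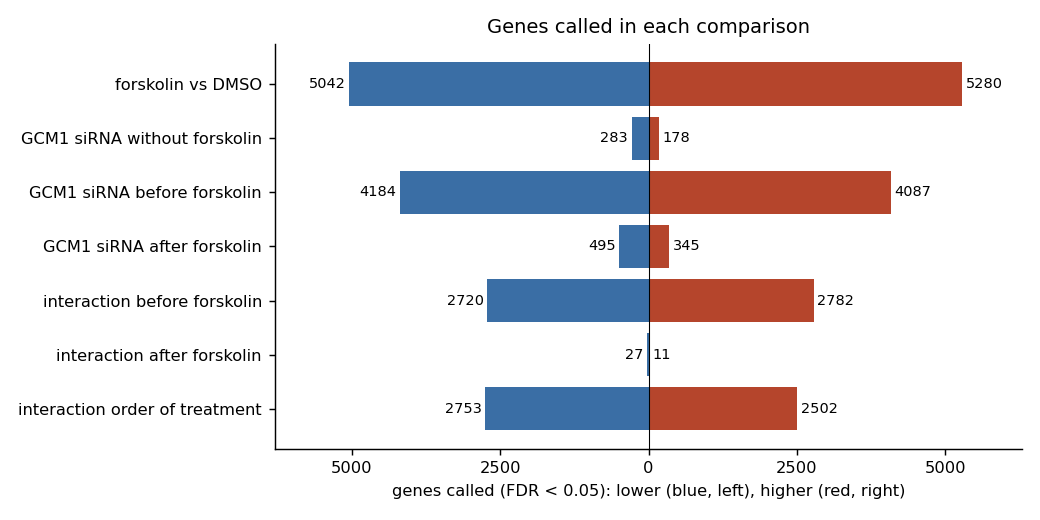
Numbers of genes called higher and lower in 7 comparisons. Bars for GCM1 siRNA before forskolin stand near those for forskolin itself.

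With GCM1 siRNA before forskolin, most genes changed by forskolin moved the other way against control siRNA. Of the 5280 genes raised by forskolin over DMSO, 3326 fell (63.0%, 1218 expected by chance), and of the 5042 lowered genes 2996 rose (59.4%, 1136 expected). Camera gave adjusted p = 5.24e-57 and 4.58e-43 for the raised and lowered sets. All camera p-values of these sets used the preset inter-gene correlation. No value with an estimated correlation or under another alternative is given for them. As the genes were chosen for a shared response to forskolin, the preset correlation may be too low and these p-values too small. Without forskolin, 217 of the raised genes fell (82.4 expected, adjusted p = 0.000267) and 97 of the lowered genes rose (49.5 expected, adjusted p = 0.00145), 314 in all, but 201 without control siRNA replicate 1, 199 without GCM1 siRNA replicate 2 and 483 by DESeq2. With GCM1 siRNA after forskolin, 416 raised genes fell (144 expected, adjusted p = 1.21e-10) and 245 lowered genes rose (95.9 expected, adjusted p = 5.72e-10), 661 in all, but 431 without forskolin-then-control siRNA replicate 1. Across all tested genes, log2 fold changes for forskolin and for GCM1 siRNA had Pearson r = -0.56 before forskolin, -0.09 without it and -0.17 after it. Of the called genes, 6322 of 8271 opposed forskolin when siRNA came first, 370 followed it and 1579 were not forskolin genes.

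**Figure D3:**
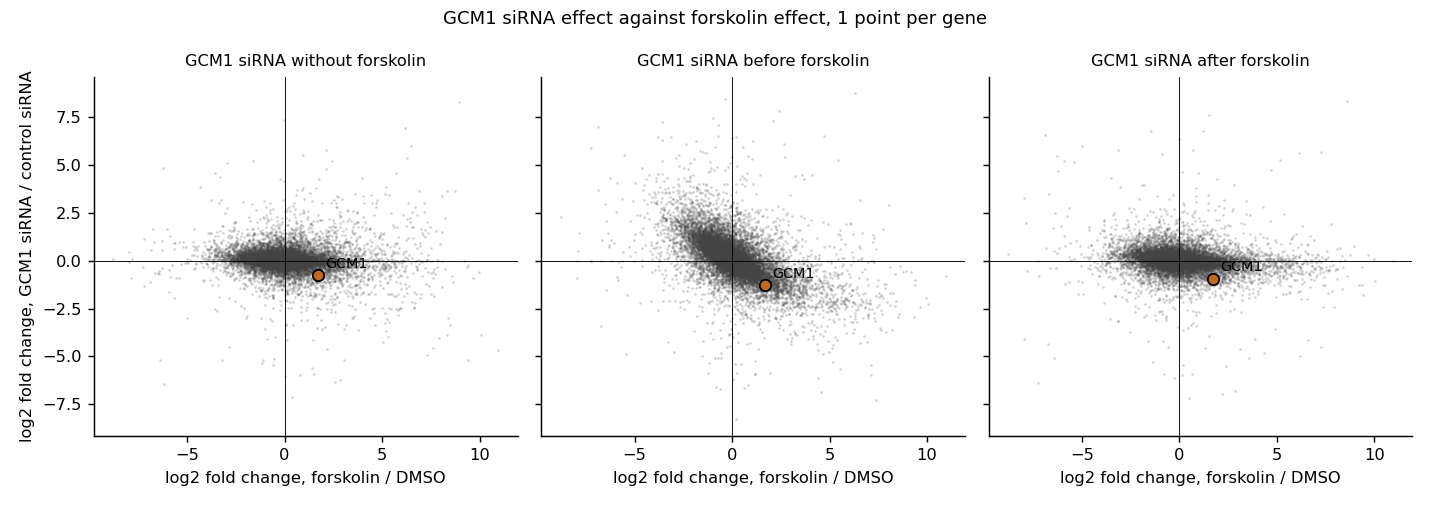
Log2 fold change with forskolin against that with GCM1 siRNA in each of 3 settings, 1 point per gene. GCM1 is marked.

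A set of 220 genes was called in the same direction by GCM1 siRNA in all 3 settings, 65 up and 155 down (2.54 expected). Without and before forskolin, 122 shared genes rose and 236 fell (40.1 and 65.3 expected), while 45 were called in opposite directions (105 expected). These 358 shared genes became 231 without control siRNA replicate 1, 227 and 238 without GCM1 siRNA replicates 2 and 3, and 546 by DESeq2. Without and after forskolin, 74 rose and 171 fell (3.39 and 7.72 expected) and 0 were opposite. Before and after it, 271 rose and 420 fell (77.7 and 114 expected) and 43 were opposite, and the 691 shared genes became 460 without forskolin-then-control siRNA replicate 1. Genes lower in all 3 settings included GCM1, PGF, LZTS1, LMO2, N4BP3, COL27A1, LINC01451, CCNE1, ERBB2, WNT10B and OVOL1. Over all tested genes the log2 fold changes correlated weakly. Pearson r was 0.14 (without and before), 0.05 (without and after) and 0.20 (before and after), and Spearman rho 0.22, 0.17 and 0.30. Most tested genes were not called without or after forskolin, so these values also hold the noise of unchanged genes.

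The effect of GCM1 siRNA before forskolin differed from its effect without forskolin at 5502 genes by the interaction test (2782 higher, 2720 lower). Time since transfection also differed between these settings, so the difference cannot be credited to forskolin alone. With library totals 4783 were higher and 1523 lower (75.8% higher, against 50.6%). CGA (log2 difference -1.82, SE 0.102, adjusted p = 5.86e-12), CGB3 (-2.15, SE 0.148), PGF (-1.19, SE 0.0718) and GCM1 itself (-0.51, SE 0.0684, adjusted p = 3.77e-06) fell more when forskolin followed, and EPCAM (3.30, SE 0.107) and NPPB (4.31) rose more. After forskolin the effect differed from that without it at 38 genes, 11 higher and 27 lower, and GCM1 was not among them (-0.19, adjusted p = 0.435). NRARP (-1.62, SE 0.167, adjusted p = 3.84e-05), NOTCH1 (-0.96, SE 0.148, adjusted p = 0.00456), PRR5 (-0.82, SE 0.12) and SFXN3 (0.80, SE 0.111) differed there also by DESeq2, with RLE factors or library totals, without the low-count filter and with any single library left out. No panel gene was called, with PGF at -0.11 (adjusted p = 0.781), SDC1 at -0.27 (adjusted p = 0.196, but 0.0252 by DESeq2) and CGA at 0.27 (adjusted p = 0.467, but 0.0127 without the low-count filter). The count of 38 fell to between 11 and 25 without any single library other than control siRNA replicate 3, for which it was 26. It rose to 306 without the low-count filter, 178 by DESeq2, 69 with a minimum mean of 5 CPM and 62 with only the compared groups in the fit. In the simulated counts this interaction recovered only 32.8% of genes changed 1.5-fold, so real differences of that size may be missed. By order of treatment, 5255 genes differed (2502 higher and 2753 lower, or 4539 and 1405 with library totals, 76.4% against 47.6%), with CGA at -2.09 (SE 0.101) and GCM1 at -0.32 (adjusted p = 9.03e-04, but -0.07 with library totals, adjusted p = 0.41).

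**Figure D4:**
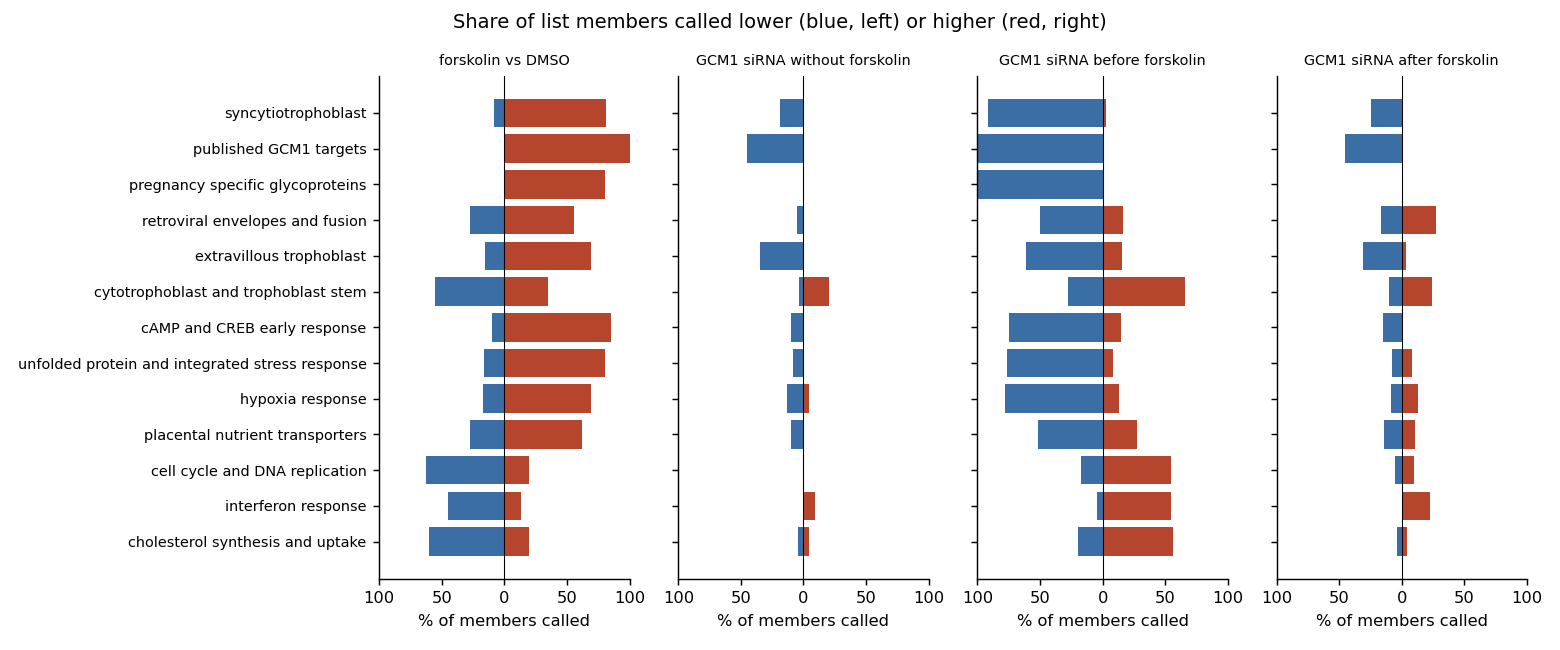
Percent of the measured members of 13 gene lists called in forskolin against DMSO and in the 3 GCM1 siRNA comparisons. Members called higher and lower are shown apart.

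Cells given forskolin and control siRNA were also compared with cells given control siRNA alone. By the labels the latter had 24 h of siRNA and no vehicle for the other 48 h. Forskolin thus cannot be told apart from the longer time. With forskolin after control siRNA, 5422 genes were higher and 5492 lower than with control siRNA alone (3302 and 8596 with library totals, 27.8% up against 49.7%). Of these, 4362 of the raised and 4096 of the lowered genes were those of the DMSO comparison (r = 0.80). CGA rose by 5.47 (SE 0.0859), CGB3 by 6.34 (SE 0.122), ERVFRD-1 by 4.34 (SE 0.0764) and GCM1 by 1.45 (SE 0.0489). With forskolin before control siRNA, 4878 genes were higher and 4803 lower (3818 and 6421 with library totals, 37.3% up against 50.4%), with CGA at 5.23 (SE 0.085), PGF at 1.56 (SE 0.0517) and ERVFRD-1 at 3.03 (SE 0.0736). GCM1 was then only 0.27 higher than in the control siRNA group (SE 0.0483, adjusted p = 5.88e-05, but 0.08 with library totals, adjusted p = 0.135). An added analysis, chosen after the data were seen, followed the 2529 genes raised at least 2-fold over DMSO. Against the same siRNA without forskolin, their median log2 fold change was 1.87 with forskolin after control siRNA and 1.10 after GCM1 siRNA. It was 1.53 and 1.42 when siRNA came after forskolin. For the 2403 genes lowered at least 2-fold the medians were -1.57 and -0.66 with siRNA first, and -0.998 and -0.929 with siRNA last.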

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

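For the number of genes changed, the tests of a single library and of library scaling were chosen only after the result was seen, as were those of a wrong label for 1 replicate and of library scaling and transfection for the fall of GCM1.

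The effect of GCM1 siRNA differed between settings by the interaction tests at 5502 genes (before forskolin against without it), 38 genes (after it against without it) and 5255 genes (before it against after it). Before against without forskolin, the log2 difference was -0.51 for GCM1, 4.31 for NPPB, 4.20 for ANGPTL2, 3.80 for SLC4A8, 3.50 for ANXA8L1 and 3.30 for EPCAM, against -3.32 for ANXA1, -3.19 for TCF15, -2.80 for MYL3, -2.77 for DEGS2 and -2.71 for MAST4. In the panel it was -2.15 for CGB3, -1.77 for SDC1, -1.19 for PGF, -2.57 for INHA, -1.82 for CGA, -1.31 for CYP19A1, -2.02 for CGB5, -1.19 for ERVW-1, -1.16 for ERVFRD-1 and 0.28 for OVOL1. List medians were -1.57 for syncytiotrophoblast genes (adjusted p = 0.00443 with an estimated correlation), -1.31 for published GCM1 targets (0.00443), -0.52 for the cAMP response (0.0286) and -0.60 for hypoxia (0.0286). Without GCM1 siRNA-then-forskolin replicate 1, in a count added after the data were seen, 27 syncytiotrophoblast genes were lower in place of 30, 6 TGF-beta genes in place of 9 and 1 mitochondrially encoded gene in place of 4, and 10 WNT genes were higher in place of 13.

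After against without forskolin, the log2 difference was 1.26 for DNAL1, 0.86 for NLRP9, 0.80 for SFXN3, 0.49 for RALBP1 and 0.47 for FOS, against -1.93 for DUOX1, -1.62 for NRARP, -1.07 for HAL, -0.96 for NOTCH1 and -0.82 for PRR5. DNAL1, DUOX1, HAL, RALBP1, FOS and NLRP9 each lost their calls without at least 7 of the 12 libraries taken singly (adjusted p up to 0.125, 0.162, 0.144, 0.119, 0.0993 and 0.0769). No gene list differed here with an estimated correlation.

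By order of treatment, 5 of 13 mitochondrially encoded genes were lower, with and without GCM1 siRNA-then-forskolin replicate 1, and the log2 difference was -0.32 for GCM1, 3.97 for RPS10-NUDT3, 3.34 for EMILIN2, 3.33 for GALNT6, 3.17 for GSDME and 3.15 for ACTA1, against -5.56 for TUBA1B-AS1, -3.47 for ATP2B3, -3.22 for PKP2, -2.96 for DEGS2 and -2.95 for S100A9. Panel values were -2.18 for CGB3, -1.49 for SDC1, -1.09 for PGF, -2.24 for INHA, -2.09 for CGA, -1.54 for CYP19A1, -2.20 for CGB5, -1.56 for HSD3B1, -1.01 for ERVW-1, -1.25 for ERVFRD-1 and 0.27 for OVOL1. TUBA1B-AS1 (adjusted p = 0.0477) lost its call under 12 alternatives (0.0505 to 0.143), and OVOL1 without GCM1 siRNA-then-forskolin replicate 1 (0.0519) or forskolin-then-control siRNA replicate 1 (0.0685). List medians were -1.72 for syncytiotrophoblast genes, -2.23 for pregnancy specific glycoproteins, -0.61 for retroviral genes, 0.61 for cytotrophoblast genes, -0.59 for extravillous genes, -1.54 for GCM1 targets, -0.72 for the cAMP response, -0.42 for the stress response, 0.73 for interferon genes and -0.72 for hypoxia genes, with adjusted p from 0.00078 to 0.0477 with an estimated correlation.

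The larger number of genes changed when GCM1 siRNA came before forskolin could rest on 1 library, on library scaling or on a blocked response to forskolin. It could also rest on time since transfection. By the labels, only this setting had 48 h of forskolin after the 24 h of siRNA. No group had the longer time without forskolin, so this cause was not tested and cannot be told apart. Without GCM1 siRNA-then-forskolin replicate 1, 5098 genes differed by order of treatment, against 5255 with all libraries, of which 4632 were called again in the same direction, which argues against a single library. With library totals in place of TMM factors 5944 differed, so the number of genes did not shrink. Library totals did move the log2 differences, by a median of 0.249, and so the share of genes higher. As such a shift can itself add calls, the number cannot exclude an effect of scaling. Of genes not called in forskolin against DMSO, 20.2% were called for GCM1 siRNA before forskolin, against 64.8% of forskolin genes. A blocked response therefore cannot be told apart from a wider effect by this test.

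Replicate 1 of the GCM1 siRNA-then-forskolin group might stand apart through ribosomal RNA, through sequence bias or through foreign RNA. Thinning its mates by the extra 18S share left 24360 genes with a count, against 22007 in replicate 1. As 18S RNA was only 1.82% of counts in replicate 1, thinning could remove few genes, so this test could hardly come out otherwise. Replicate 1 also had the largest total of its group (24537198 counts, against 20515869 and 23331802 in replicates 2 and 3). With so small an 18S share, replicate 1 had no fewer counts left for other genes, which argues against dilution by 18S RNA. GC content and transcript length explained 0.307% of the variance of its difference from its mates (1.53% at most for other samples), which argues against such a bias. The slope of that difference on the difference of the control siRNA-then-forskolin group from the same mates was 0.152 (r = 0.166). This argues against a library of that group under a wrong label, for which it would be near 1. Other groups were not tested in this way. As the mates entered both differences, their noise alone can give a positive slope. A small admixture of control RNA cannot be told apart from other causes by this slope.

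GCM1 was lower after forskolin then control siRNA than straight after forskolin (log2 difference -1.26, SE 0.0486, adjusted p = 4.74e-15). With library totals the difference was -1.15, which argues against scaling. Control siRNA alone left GCM1 0.17 above DMSO, but those cells had no forskolin, so an effect of transfection after forskolin stays open. GCM1 lay at percentile 12.1 of the genes raised at least 2-fold by forskolin, whose median difference was -0.34 (quartiles -0.84 and 0.11). The forskolin libraries by which these genes were chosen also entered their difference, which by itself can lower the median. A general fading of the response therefore cannot be told apart from a fall particular to GCM1. By the labels, 24 h of siRNA followed the 48 h of forskolin, so an effect of this later time stays open. Withdrawal of forskolin was not recorded and stays open too.

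Real groupings were set against other splits of the same libraries. Of the 10 splits in each pair of groups, 1, the real one, gave as many genes, which is too few splits for a share under 0.05. The highest other split called 0 genes against 10322 (forskolin against DMSO), 1 against 461, 15 against 8271 and 1 against 840 (GCM1 siRNA without, before and after forskolin), and 0 against 10914 and 9681 (forskolin after and before control siRNA). For each interaction 10 of 100 splits gave as many genes as the real one, so that by this count chance cannot be excluded for the 5502, 38 and 5255 genes (highest other split 6164, 284 and 6386). Of these 10, 1 was the real grouping and 9 were among the 18 splits that kept the real siRNA labels in 1 of the 2 treatments and so its effect. The 81 splits that parted both called at most 1, 2 and 7 genes. Splits that part the real groups, here and in the pairs, mix them, so that real effects add to the spread and lower the calls. Their low counts therefore do not measure chance.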

How the results depend on the processing

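No GCM1 value, named gene or gene list that was called was called with the opposite sign under the alternatives run for it. Limma-voom was run for counts of calls and for calls shared with the main test, the fit of only the compared groups for counts alone, and the minimum mean of 5 CPM for counts and overlaps alone. Of the counts of called genes 119 of 153 alternatives stayed within 1.5 times the value, and of the overlaps 111 of 125. The outcome, called or not and its sign, stayed the same for 115 of 117 GCM1 values, 2332 of 2479 named gene values and 954 of 1008 gene list values. The causes of the shifts below were not tested. DESeq2 shared 10198 of 10322, 458 of 461, 8096 of 8271 and 828 of 840 calls for forskolin and for GCM1 siRNA without, before and after it. Limma-voom shared 10001, 408, 7838 and 784 of them, and the fit with the replicate block 10189, 429, 8095 and 791. Without GCM1 siRNA-then-forskolin replicate 1, 7191 of the 8271 calls before forskolin were shared.

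With a 2-fold minimum added, the counts were 4932 for forskolin against DMSO, 39, 2919 and 54 for GCM1 siRNA without, before and after forskolin, 5632 and 4062 for forskolin after and before control siRNA, and 1938, 4 and 1791 for the interactions before, after and by order. With forskolin genes changed at least 2-fold, the reversal before forskolin held 3227 genes, and the overlaps of GCM1 siRNA comparisons 219 (without and before), 147 (without and after), 439 (before and after) and 142 (all 3).

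With library totals, GCM1 differed by 0.0807 for forskolin before control siRNA and by -0.0742 by order of treatment. Adjusted list p-values were then 0.184 for mitochondrial genes in forskolin against DMSO, 0.0819 for hypoxia without forskolin, 0.453 for mitochondrial genes before it, and 0.0395 and 0.0145 for hypoxia and mitochondrial genes after it. Without the low-count filter, 738 genes were called for GCM1 siRNA without forskolin and 306 for the interaction after it, and adjusted list p-values were 0.0358 for cytotrophoblast genes in forskolin against DMSO, 0.165 for blood markers without forskolin, and 0.0114 and 0.0263 for hypoxia and mitochondrial genes after it. The interaction after forskolin called 69 genes with a minimum mean of 5 CPM and 62 with only the compared groups in the fit.

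Samples with the same replicate number correlated little in their differences from group means (r from -0.0563 to 0.0525, median 0.00398, over 84 pairs, 0 above 0.1, against -0.0579 to 0.0571, median -0.00353, over 168 other pairs). Of 24 samples, 13 correlated best with their own number. This is more than unrelated numbers would give on average, so a weak pairing stays open. As no pair passed 0.1, the samples were not treated as paired. With the replicate number as a block the counts were 10294, 439, 8211 and 837 for forskolin and for GCM1 siRNA without, before and after it and 33 for the interaction after it, and mitochondrial genes after forskolin had adjusted p = 0.00456. The block ended the calls of ALG14 without forskolin (adjusted p = 0.0608), of KRT24 after it (0.0511), of DNAL1 (0.0516), DUOX1 (0.0788) and HAL (0.0544) for the interaction after it, and of TUBA1B-AS1 by order of treatment (0.0505).

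With an estimated correlation, lists in forskolin against DMSO had adjusted p of 0.0912 (pregnancy specific glycoproteins), 0.227 (retroviral), 0.240 (steroid), 0.0674 (cholesterol), 0.0674 (cell cycle), 0.0674 (interferon), 0.0674 (hypoxia) and 0.474 (mitochondrial). Without forskolin these were 0.0541 (syncytiotrophoblast), 0.103 (cholesterol), 0.273 (stress response), 0.274 (hypoxia), 0.0502 (p53) and 0.0541 (TGF-beta), and before it 0.103 (retroviral), 0.211 (cholesterol), 0.0508 (cell cycle), 0.137 (transporters), 0.166 (WNT) and 0.485 (mitochondrial). After forskolin they were 0.194 (cytotrophoblast), 0.0641 (cell cycle), 0.0872 (interferon) and 0.157 (junctions).

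In the simulation without forskolin, drawn with dispersions estimated by edgeR, 20.2% of the calls of DESeq2 were false. This does not show the share of false calls in the real samples. There DESeq2 called 744 genes without forskolin and 178 for the interaction after it, with 483 reversed genes without forskolin and 546 in the overlap of without and before. It gave no adjusted p to 3870 and 6682 genes of these comparisons through its own filter. Its adjusted list p-values were 0.319 and 0.192 for pregnancy specific glycoproteins and mitochondrial genes in forskolin against DMSO, and before forskolin 0.0644 (pregnancy specific glycoproteins), 0.0503 (cholesterol), 0.00363 (TGF-beta) and 0.141 (mitochondrial).

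With each library left out in turn, the counts ran from 276 to 367 without forskolin, from 544 to 629 after it and from 11 to 26 for the interaction after it, against 7556 to 7927 before it. Reversed genes ran from 199 to 332 without forskolin and from 431 to 659 after it, and overlaps from 227 to 412 (without and before) and from 460 to 772 (before and after). Adjusted list p-values ran from 0.0258 to 0.0573 for retroviral genes in forskolin against DMSO. Without forskolin they ran from 0.0397 to 0.697 (mitochondrial), 0.0104 to 0.0689 (hypoxia) and 0.0239 to 0.638 (steroid). Before it they ran from 0.00213 to 0.159 (mitochondrial), 0.0157 to 0.0684 (WNT) and 0.0173 to 0.0552 (cholesterol), and after it from 0.0160 to 0.252 (mitochondrial) and 0.0172 to 0.536 (stress response).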

Other observations

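NOTCH1 and its target NRARP were lower with GCM1 siRNA after forskolin, but without forskolin neither was called (adjusted p = 0.815 and 0.0615), and NRARP was at 12.4 ± 0.348 CPM with GCM1 siRNA and 9.19 ± 0.855 with control siRNA. After forskolin NOTCH1 was at 165 ± 7.42 CPM in the forskolin-then-GCM1 siRNA group and 345 ± 9.27 in the forskolin-then-control siRNA group (interaction -0.96, SE 0.148, adjusted p = 0.00456), and NRARP at 12.7 ± 0.747 and 29 ± 1.84 (interaction -1.62, SE 0.167). Both were also lower with GCM1 siRNA before forskolin, NOTCH1 at 146 ± 26.3 against 696 ± 53.9 and NRARP at 22.8 ± 3.66 against 66.5 ± 5.81. Both interactions kept their calls with any single library left out.

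Of the marker genes of other cell types, CSF1R had a mean of 200 CPM over the 24 samples and CDH5 326, while COL1A1 had 24.2, VWF 7.72, PDGFRB 4.04 and PECAM1 1.09, and the others were under 0.39.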
